A study of Mus musculus with 2 samples.

How the data were processed

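Monomethylation of histone H3 at lysine 4 (H3K4me1) was measured by chromatin immunoprecipitation and sequencing in hindbrain tissue from mouse embryos at day 13.5. The tissue was pooled from male and female embryos, per the labels. The series holds 1 group of 2 biological replicates. Replicate 1 was made from 1 technical replicate and replicate 2 from 2, per the labels. Library fragments were selected at 300 to 500 bp, per the labels.

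The deposited files are 4 peak lists in the narrowPeak format on the mm10 build: a list for each replicate, a list called on both replicates pooled, and a replicated list derived from the other lists, per the text deposited with the lists. Peaks were called against control libraries, per the same text. The aligner, the peak caller and the overlap rule behind the replicated list are not given in the sources used here. The deposited signal value of a peak is the authors' measure of its strength and was never negative. Its scaling is not given in the sources used here. The lists also hold the authors' −log10 p and −log10 q of each peak and a deposited display score, which rises with −log10 p. These values were used only to rank, filter or describe peaks within a list, with some exceptions between replicates. These were the rank correlations of signal values and of −log10 p, the comparison at common −log10 p cut-offs and the lowest −log10 p of each list. Overlap shares at a common signal value or a common −log10 q were also compared. A common signal value assumes the same scaling in both replicates, which is not known. The files give no read counts, so the sequencing depth of each library is unknown and no interval that needs it is given.

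Peaks on chromosomes 1 to 19 and X were used. A peak was counted as shared when it overlapped a peak of the other list by at least 50% of the length of either peak. The same share was computed for peaks placed at random on their chromosome outside assembly gaps, in 20 shuffles. Gene models were the protein-coding genes of GENCODE release M21, and the sequence was the GRCm38 reference, which is the same assembly as mm10. On all 20 chromosomes no peak or gene ended past the reference length. After 1 gene model was kept per symbol, 21728 genes remained. A peak was assigned by its midpoint to a promoter (within 1 kb of a start site of a protein-coding transcript), then an exon, an intron or intergenic sequence. A promoter was called CpG-rich when the 500 bp on each side of the start site had a CpG observed-to-expected value of at least 0.6 and a GC content of at least 50%.

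For each gene, the percentage of the gene body plus 20 kb on each side that lay in peaks was computed and turned into a percentile among the 200 protein-coding genes closest in length. A window can hold peaks of neighbouring genes, which counted as well. A member of a gene list was called high at the 90th percentile or above and low at the 10th or below. The median percentile of each of 17 lists was compared with 10000 random lists in which each member was replaced by one of its 200 matched genes, in a two-sided permutation test with Benjamini-Hochberg adjustment over the 17 lists. Differences between lists were tested by exchanging members in a two-sided permutation test with 100000 resamples, adjusted over 3 comparisons. Genes are the units of these tests, so the p-values describe these libraries and not the spread between embryos. An adjusted p under 0.05 was the threshold. Peaks 1 kb or less apart were joined into regions.

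The gene lists, the main test of each comparison and the rule for named genes were fixed before the data were examined. Tests of explanations and alternatives that were chosen later are named as such with their results. The rule named the 2 members of each list with the highest percentile and the 1 with the lowest, the 10 genes with the highest covered percentage, the 10 peaks with the highest signal value and the 10 widest joined regions. Among the 10 genes and among the 10 peaks, only the first of those within 200 kb of each other was named. Members of the gene lists were named without this spacing. Other values are given as mean ± SD over the 2 replicates' own lists.

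The list test was checked on simulated peaks. With shuffled peaks, 4.33% of 300 random lists of 18 genes had a permutation p under 0.05, and 2.67% of 300 pairs of such lists did in the difference test. Whole peaks of a fixed width were then added to the windows of 18 members, aiming at 1.25-fold, 1.5-fold and 2-fold the average covered bases. At these aims 10%, 55% and 100% of 20 lists were recovered. In short windows the bases added could differ from the aim, so the folds are nominal. The check did not model the link of coverage to GC content or list members that share windows. Overlap counts were checked against bedtools 2.31.1 and were equal. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

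The alternatives covered the overlap rule, stricter peak thresholds, the pooled list, each replicate's own list, other windows around genes, other promoter and joining distances, 1 list member per 200 kb, and matching on GC content. Peaks on unplaced contigs were left out of the comparisons.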

Results

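H3K4me1, a histone mark found at enhancers and beside active promoters, was mapped in the hindbrain of mouse embryos at day 13.5. The hindbrain gives rise to the cerebellum, pons and medulla. The series holds 1 group of 2 biological replicates, so the comparisons are between replicates, between parts of the genome and between groups of genes. Replicate 1 had 241978 peaks and replicate 2 had 201100 (221539 ± 28905, mean ± SD, n = 2). The deposited pooled list held 248596 peaks and the replicated list 152885. Replicated peaks on chromosomes 1 to 19 and X had a median width of 634 bp and covered 137.8 Mb, or 5.38% of the sequence. Sequencing depth is unknown, since the files give no read counts.

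The first question was how far the replicates shared their peaks. The strongest sites were nearly all shared, and the share was lower among weaker ones. Of the peaks of replicate 1, 55.2% overlapped a peak of replicate 2, and of those of replicate 2, 77.1% overlapped a peak of replicate 1. Shuffled peaks gave 6.11% and 7.62%. With the peaks of each replicate ranked by signal value and split into 10 equal parts, the shares were 99.6% and 99.9% in the strongest part and 23.2% and 59.3% in the weakest. Peaks of replicate 1 without a partner had a median signal value of 2.68, against 3.62 for shared ones, and were 256 bp wide against 592 bp. In replicate 2 the medians were 2.77 and 3.32. Replicate 1 covered 143.0 Mb and replicate 2 covered 104.2 Mb, and 85.7 Mb lay in peaks of both.

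**Figure D1:**
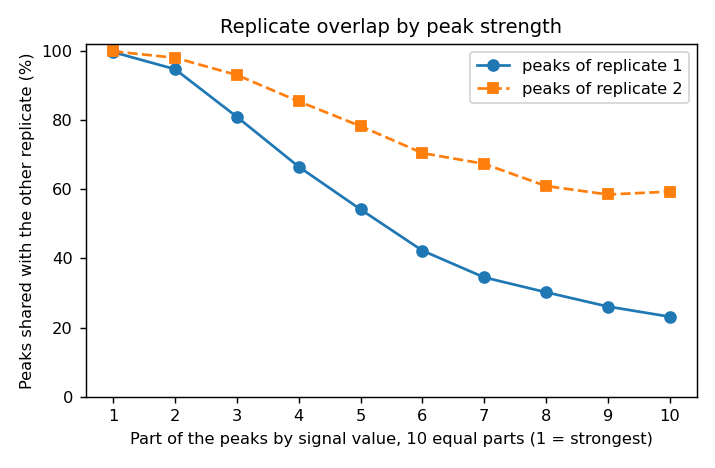
Percentage of each replicate's peaks that overlapped a peak of the other replicate (vertical axis), in 10 equal parts of the peaks ranked by signal value (horizontal axis, 1 is the strongest). The share fell from 99.6% to 23.2% in replicate 1 and from 99.9% to 59.3% in replicate 2.

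When each replicate was limited to its strongest 50000 peaks, 66.5% of those of replicate 1 and 74.0% of those of replicate 2 overlapped one in the other set. Of the same 50000 peaks, 96.8% and 98.2% overlapped any peak of the other replicate. Rho was taken across the 129450 replicated peaks that touched a peak in both replicates, with the strongest such peak of each. Their signal values in the 2 replicates had a Spearman's rho of 0.636, where peaks are not independent replicates. Replicated peaks that touched none in a replicate were left out. All 152883 replicated peaks on these chromosomes were in the pooled list with the same position and signal value, and 84.3% overlapped a peak in both replicates. The other 24013 did not meet that overlap in both.

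The second comparison was of where the mark lay. Introns held 54.3% of replicated peaks, intergenic sequence 31.3%, promoters 11.2% and exons outside promoters 3.23%. Promoters held 4.22 times the share of shuffled peaks, introns 1.46 times, exons 1.28 times and intergenic sequence 0.544 times. The replicates' own lists had 9.80% ± 1.04 of peaks at promoters (SD, n = 2), with shuffled peaks at 2.64%. Among the strongest 10000 replicated peaks 20.7% were at promoters, and among the weakest 10000 it was 5.42%.

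The strongest peaks lay inside or just beside genes. Their midpoints were between 437 bp (Prrt2) and 25589 bp (Ncor2) from the nearest gene start, with 1 start taken per gene. Starts of other transcripts may lie nearer. The peak with the highest signal value, 15.24, was on chromosome 15 from 75910093 to 75913615. Its midpoint was in an exon of Tigd5 and 2119 bp from the start of that gene. A peak of 14.0 lay on chromosome 8 from 121591074 to 121593801 in an exon of Map1lc3b, which encodes an autophagosome protein. One of 13.9 lay on chromosome 10 from 80151587 to 80157927 in an intron of Midn. Next came Zfp251 at 13.5 and Atf4, which encodes a transcription factor of the stress response, at 13.4. The Atf4 peak was intergenic, on chromosome 15 from 80256294 to 80258992. The Ncor2 peak, at 13.4, was 16015 bp wide and Soga1 and Nomo1 both had 13.3. Peaks nearest to Adam1a and Prrt2 both had 13.1. Of these 10 peaks, 1 had its midpoint within 1 kb of a start site, that of Prrt2.

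Around start sites the mark formed 2 flanks with a gap between them at CpG-rich promoters, and no such gap at other promoters. Of 9731 genes with a CpG-rich promoter, 15.1% had a replicated peak at the start site itself, 70.7% had one 1 kb downstream and 42.0% had one 1 kb upstream. The share 1 kb downstream was 4.68 times that at the start site. In the replicates' own lists the values were 12.9% ± 1.95 at the start site and 64.8% ± 5.65 downstream (SD, n = 2), a difference larger than the spread between replicates. Of 11997 genes with other promoters, 20.9% had a peak at the start site, 20.0% had one 1 kb downstream and 8.87% had one 1 kb upstream.

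**Figure D2:**
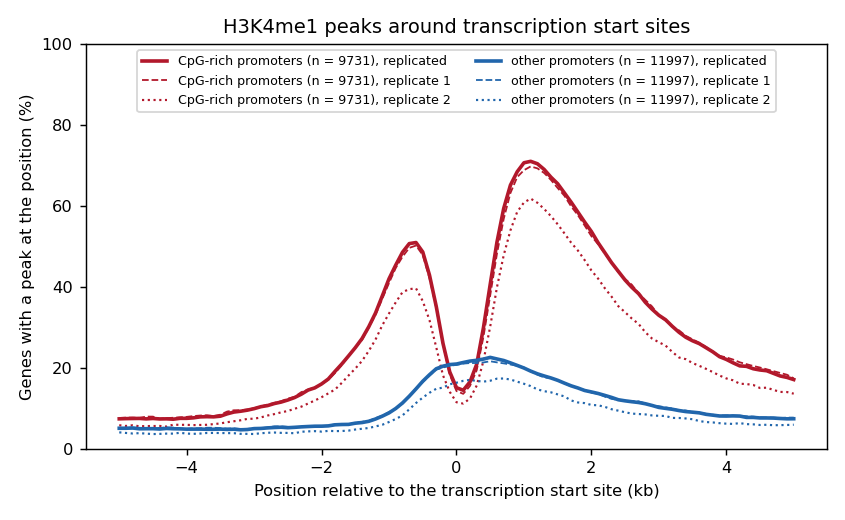
Percentage of protein-coding genes with a peak at each position (vertical axis) from 5 kb upstream to 5 kb downstream of the start site (horizontal axis, kb), for CpG-rich (red) and other promoters (blue), with solid lines for the replicated list, dashed for replicate 1 and dotted for replicate 2. At CpG-rich promoters the replicated list went from 15.1% at the start site to 70.7% at 1 kb downstream.

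The third comparison asked which groups of genes lay in H3K4me1-rich surroundings. Genes listed as hindbrain regional regulators, anterior Hox genes, and genes of neural progenitors, of neurons in general and of hindbrain neurons were covered more than genes of their length. So were signalling genes and housekeeping genes. The lists for blood, vessels, muscle, liver and other organs did not pass the test with this window. Over all 21728 genes, the median window was 6.27% covered, and 4292 genes had no replicated peak in the window. A gene's covered percentage also rose with the GC content of its window, with a Spearman's rho of 0.747 across genes, which are not independent replicates.

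**Figure D3:**
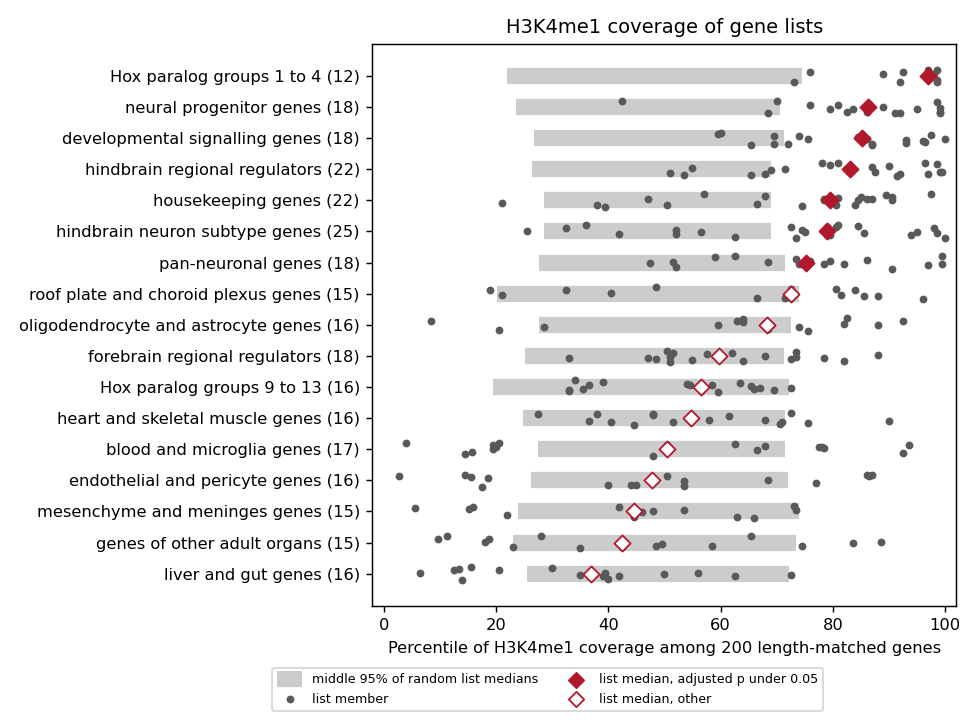
Percentile of each list member's covered percentage among 200 genes matched on length (horizontal axis) for 17 lists (vertical axis, number of members in brackets). Grey dots are members, diamonds are list medians (filled where the adjusted p was under 0.05) and grey bars span the middle 95% of random list medians. Filled medians run from 75.25 to 97.

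Hindbrain regional regulators had a median percentile of 83 (82.4 ± 5.13 in the replicates' own lists, SD, n = 2), with 8 of 22 members high and 0 low (permutation p = 0.0008, adjusted p = 0.0034). Nr2f2, an orphan nuclear receptor on chromosome 7 from 70351944 to 70366735, had 42.1% of its window covered (35.4% ± 5.71 in the replicates' own lists). Nr2f1, on chromosome 13 from 78188973 to 78199757, had 47.2% (41.9% ± 7.15). The member with the lowest percentile, 51, was Atoh1, a proneural gene of the rhombic lip, with 11.5% covered. Forebrain regional regulators had a median of 59.75 with 0 of 18 members high (permutation adjusted p = 0.619). Their highest were Lhx2 with 16.6% and Gsx2 with 23.8%, and the lowest was Arx on chromosome X with 4.47% (5.90% in replicate 1 and 2.78% in replicate 2). The hindbrain list lay 23.25 percentile points above the forebrain list (permutation p = 0.00184, adjusted p = 0.00276). Whether members of either list are also used in other brain regions was not tested, so the difference was not tied to regional identity. With 50 kb on each side of genes, the hindbrain list had a median of 71.75 and a permutation adjusted p of 0.0782.

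Hox genes, which set position along the body axis, were split by paralog group. Groups 1 to 4, used in the hindbrain, had a median percentile of 97 (95 ± 3.54 in the replicates' own lists, SD, n = 2) and 9 of 12 members were high (permutation adjusted p = 0.00227). These genes lie in 4 clusters and share windows, and with 1 gene per 200 kb the list had 4 members, a median of 82.5 and no call (permutation adjusted p = 0.175). The member kept in each cluster was the first in list order: Hoxa1, Hoxb1, Hoxd1 and Hoxc4. That value therefore stands mostly for group 1, and other choices were not tried. Hoxa4, on chromosome 6 from 52189671 to 52191753, had 48.7% of its window covered (38.3% ± 13.7). Hoxb2, on chromosome 11 from 96350525 to 96354012, had 39.2% (37.2% ± 7.55), and Hoxb1 was lowest with 18.99%. Groups 9 to 13, used in the trunk and limbs, had a median of 56.5 with 0 of 16 high (permutation adjusted p = 0.7998). Their highest percentiles were those of Hoxa9 (17.4% covered, 13.8% ± 5.01 in the replicates' own lists) and Hoxd13 (12.6%, 9.41% ± 1.46), and the lowest, 33, was shared by Hoxc13 (1.74%, 2.38% ± 0.513) and Hoxa13 (2.07%, 3.37% ± 1.17). The groups differed by 40.5 percentile points (permutation p = 0.00029, adjusted p = 0.00087). With 1 gene per 200 kb the difference was 19.75 between 4 genes and 4 (permutation adjusted p = 0.0860). The genes kept from groups 9 to 13 were Hoxa9, Hoxb9, Hoxc9 and Hoxd9, and 4 genes against 4 allow few exchanges. With random lists matched on GC content as well, groups 9 to 13 had a median of 13 and were below them (permutation adjusted p = 0.00068), but their 16 members share windows. With 1 gene per 200 kb as well, 4 members had a median of 22.25 and no call (permutation adjusted p = 0.252). In that setting, chosen after the data were examined, groups 1 to 4 had a median of 96 with 4 members (permutation adjusted p = 0.00425).

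**Figure D4:**
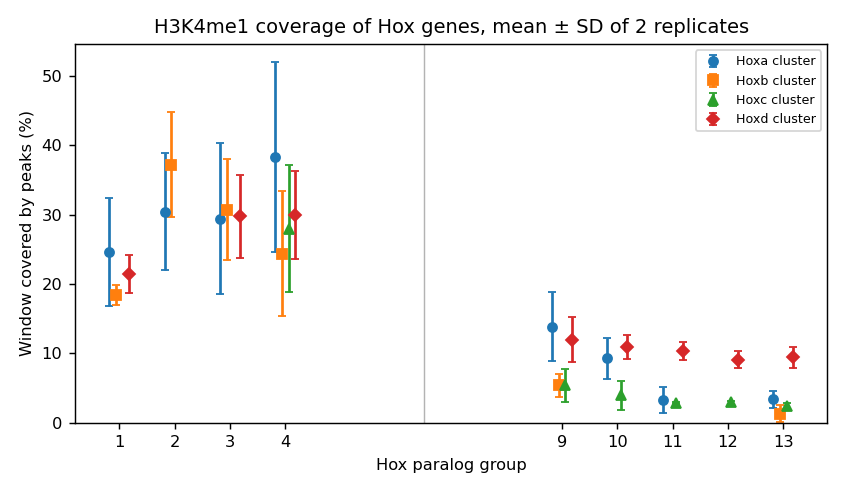
Percentage of each Hox gene's window covered by peaks (vertical axis, mean ± SD of the 2 replicates' own lists) by paralog group (horizontal axis), with a marker for each cluster. The grey line parts groups 1 to 4 from groups 9 to 13, and groups 5 to 8 were not in the lists. Hoxa4 lay at 38.3% and Hoxc13 at 2.38%.

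Genes of neural progenitors had a median percentile of 86.25 with 7 of 18 high (permutation adjusted p = 0.00227). Notch1, a receptor that keeps progenitors undifferentiated, had 52.1% of its window covered on chromosome 2 from 26457903 to 26516663 (48.6% ± 6.08, SD, n = 2). Sox2, a transcription factor of neural stem cells, had 48.0% on chromosome 3 from 34650405 to 34652461 (39.2% ± 8.26). Sox3, on chromosome X, was lowest with 5.80% (7.17% in replicate 1 and 2.18% in replicate 2). Genes of hindbrain neuron subtypes had a median of 79 with 5 of 25 high (permutation adjusted p = 0.00476). Lmx1b, required for serotonergic neurons, had 53.7% on chromosome 2 from 33560965 to 33640511 (46.2% ± 7.51). Slc32a1, the vesicular transporter of inhibitory transmitters, had 44.8%, and Slc17a6, a vesicular glutamate transporter, was lowest with 3.45%. With 50 kb on each side this list had a median of 70 (permutation adjusted p = 0.0839).

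Pan-neuronal genes had a median percentile of 75.25 with 4 of 18 high, just past the threshold (permutation adjusted p = 0.0495). Rbfox3, which encodes the neuronal protein NeuN, had 51.6% on chromosome 11 from 118489762 to 118911597 (46.0% ± 5.47, SD, n = 2). Celf4, a neuronal RNA-binding protein gene, had 49.4%, and Ina, a neuronal intermediate filament gene, had the lowest percentile, 47.5, with 8.74% covered. The call was lost without replicate 1 (median 75.25, permutation adjusted p = 0.0505), with 50 kb on each side (72.25, 0.0839), with 1 member per 200 kb (76, 0.0635) and without chromosome X (75.5, 0.0636). Developmental signalling genes had a median of 85.25 with 6 of 18 high (permutation adjusted p = 0.00227). Rara, a retinoic acid receptor gene, had 55.4% on chromosome 11 from 98927818 to 98974942 (53.2% ± 4.88). Ptch1, the Hedgehog receptor gene, had 34.9%, and Spry2 had the lowest percentile, 59.5, with 6.73% covered. Housekeeping genes had a median of 79.5 with 3 of 22 high (permutation adjusted p = 0.0068). Eef2, a translation elongation factor gene, had 38.9% and Rplp0 26.8%, and Hprt on chromosome X was lowest with 1.44%. Matched on GC content as well, the signalling list had a median of 64.5 (permutation adjusted p = 0.396) and the housekeeping list 71.25 (permutation adjusted p = 0.0685). The hindbrain regional list lay 3.5 points above the housekeeping list, which the permutation test did not separate from 0 (adjusted p = 0.501). With GC matching, chosen for this difference after the data were examined, it was 16.75 points (permutation adjusted p = 0.0161; 0.0161 to 0.989 over all alternatives).

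Lists of other cell types and organs did not pass the threshold with gene body plus 20 kb, and 2 of them did with other windows. Roof plate and choroid plexus genes had a median percentile of 72.5 with 1 of 15 high (permutation adjusted p = 0.138). They passed with 5 kb on each side (median 78, permutation adjusted p = 0.0317) and with 10 kb on each side of the start site (80.5, permutation adjusted p = 0.0233). Wnt1, a signal of the midbrain-hindbrain boundary and roof plate, had 39.4% covered, Foxj1 26.9% and Folr1 0.641% (0.898% in replicate 1 and 0% in replicate 2). Oligodendrocyte and astrocyte genes had a median of 68.25 with 1 of 16 high and 1 low (permutation adjusted p = 0.216). Mbp, which encodes a myelin protein, had 21.6% (23.5% in replicate 1 and 12.5% in replicate 2), Cspg4 18.9% and Plp1, on chromosome X, 0%. Heart and skeletal muscle genes had a median of 54.75, with Mylpf at 24.7%, Tnni3 at 15.4% and Tbx5 at 2.77% (permutation adjusted p = 0.7998). Blood and microglia genes had a median of 50.5 with 2 of 17 high and 1 low (permutation adjusted p = 0.858). Cd68 had 33.0% covered (percentile 93.5), Hba-a1 3.97% (percentile 92.5 among genes of its length) and Itgam 0%. Endothelial and pericyte genes had a median of 47.75, with Pdgfrb at 19.9% (18.9% in replicate 1 and 12.04% in replicate 2), Eng at 17.1% and Tek at 0% (permutation adjusted p = 0.858). Mesenchyme and meninges genes had a median of 44.5, with Foxc1 at 14.99%, Foxc2 at 16.3% and Col3a1 at 0% (permutation adjusted p = 0.7998). Genes of other adult organs had a median of 42.5, with Sftpc at 24.5%, Rho at 21.7% and Ambn at 0% (permutation adjusted p = 0.7998). Liver and gut genes had a median of 37, with Hnf1a at 11.6%, Vil1 at 8.96% and Alb at 0% (permutation adjusted p = 0.497). With 5 kb on each side they were below random lists, with a median of 20.375 (permutation adjusted p = 0.0149).

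Over the whole genome, the gene whose window had the highest covered percentage was G430095P16Rik (chromosome 8 from 84723007 to 84726844) with 82.0% (74.5% ± 10.1 in the replicates' own lists, SD, n = 2). This gene is 3838 bp long, so most of its window is flanking sequence that can hold peaks of neighbouring genes. The same holds for Thtpa (4203 bp), Btg2 (3951 bp) and Midn (10097 bp). It also holds for Pipox (13482 bp), Flrt1 (13729 bp), Pcdhgc5 (22361 bp) and Cxxc5 (32292 bp). Of the 10 genes named here, only Msi2 and Gse1 were longer than their flanks together. Msi2, an RNA-binding protein gene of neural progenitors, had 73.7% over a gene of 379132 bp on chromosome 11 from 88339382 to 88718513 (67.0% ± 7.46). Cxxc5 had 73.1% on chromosome 18 from 35829397 to 35861688, Pipox 72.5% and Gse1 69.3%. They were followed by Pcdhgc5, a clustered protocadherin gene, with 67.5% and Thtpa with 66.7%. Midn had 66.2%, Flrt1 65.7% and Btg2, an antiproliferative gene of neurogenic progenitors, 65.4%.

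Peaks 1 kb or less apart were joined into 94275 regions, of which 955 were at least 10 kb wide and 142 at least 20 kb. The widest, 93494 bp, was on chromosome 4 from 106912999 to 107006492 and overlapped Ssbp3, which encodes a cofactor of LIM-domain transcription factors. Peaks filled 95.3% of it in the replicated list, 92.3% in replicate 1 and 86.3% in replicate 2. The next were at Ccdc85c (66301 bp, chromosome 12 from 108208648 to 108274948) and Ncor2 (61376 bp, chromosome 5 from 125119749 to 125181124), a transcriptional corepressor gene. Slit1, an axon guidance gene, had a region of 53824 bp, Basp1 52726 bp and Msi2 50142 bp. Map4k4 had 49777 bp, Map1b, a microtubule protein gene of growing axons, 49627 bp, Tet3 47385 bp and Ebf3 47149 bp. In replicate 2 alone 628 regions were at least 10 kb wide.

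Chromosome X stood apart from every autosome. Replicated peaks covered 0.503% of it, against 3.85% of chromosome 3, the lowest autosome, and 9.29% of chromosome 11, the highest. The ratio of X to the median autosome was 0.0864, and it was 0.0863 ± 0.0156 in the replicates' own lists (SD, n = 2). The lowest members of several lists (Arx, Sox3, Plp1 and Hprt) were on this chromosome. No pooled peak was on chromosome Y.

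**Figure D5:**
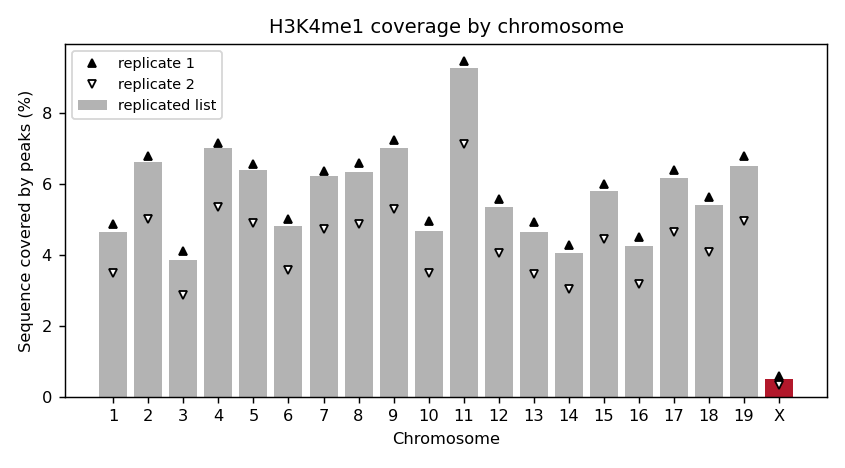
Percentage of each chromosome's sequence outside assembly gaps covered by peaks (vertical axis) by chromosome (horizontal axis). Bars are the replicated list (X in red) and triangles the 2 replicates' own lists. X is at 0.503% and the autosomes lie between 3.85% and 9.29%.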

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

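The pooled list held 6 peaks on unplaced contigs, which no comparison used, and the replicated list held 2. They are listed only because no control samples were analysed here to set them against and the count is above 3. The origin of these peaks was not tested.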

How the results depend on the processing

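Of 241 values recomputed under alternatives, 183 kept their direction and side of the threshold or stayed within the limit set for untested values. That limit was the spread between replicates, or a fixed ratio for the number of regions. The values without a replicate are those the spread was computed from, so against it they are no separate check. Lists without a call that stayed without one on the same side also count among the 183. For overlap shares and rho it was an interval across peaks, which treats peaks as independent. Merging peaks first left the overlap shares at 55.2% and 77.1%, as peaks within a list do not overlap. The alternatives added after the data were examined were chromosome X left out, for the Hox lists GC matching together with 1 member per 200 kb, and for differences between lists also GC matching, 1 member per 200 kb and −log10 q of at least 5. Causes were not tested unless named. Depth is unknown, so its effect on weak peaks could not be measured.

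The shared share of replicate 1 and replicate 2 was 60.2% and 82.8% with an overlap of 1 bp, 37.8% and 45.5% with 50% of both peaks, 56.3% and 77.6% with −log10 q of at least 2, and 59.0% and 80.3% with a signal value of at least 4. For the strongest peaks it was 64.6% and 68.9% with 20000 peaks and 69.4% and 77.4% when ranked by −log10 p. With 1 bp, 84.7% of replicated peaks overlapped both replicates. Spearman's rho was 0.681 with −log10 p (95% bootstrap interval of the main value, 0.632 to 0.640). The promoter share and its ratio to shuffled peaks were 20.4% and 3.39 within 2.5 kb, 12.9% and 4.87 with −log10 q of at least 5, and 8.53% and 3.26 in the pooled list. Leaving out a replicate gave 9.06% to 10.5% and 3.43 to 3.98. The CpG-rich ratio of 1 kb downstream to the start site was 4.82 to 5.29 without a replicate. Regions of at least 10 kb numbered 3610 when peaks within 3 kb were joined, 1501 in the pooled list and 628 to 1161 without a replicate.

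With gene body plus 50 kb, 3 lists lost their call in the permutation test: hindbrain regional regulators (median 71.75, adjusted p = 0.0782), pan-neuronal genes (72.25, 0.0839) and hindbrain neuron subtype genes (70, 0.0839). Genes of other adult organs had 49.5 there. With 1 member per 200 kb, Hox groups 1 to 4 had 82.5 with 4 members (permutation adjusted p = 0.175; 0.00068 to 0.175 over all alternatives) and pan-neuronal genes 76. The pan-neuronal call was also lost without replicate 1 (75.25 to 76.5 over the replicates left out) and without X (75.5), with permutation adjusted p of 0.00068 to 0.0839 over all alternatives. With GC matching, calls were lost for signalling genes (64.5) and housekeeping genes (71.25), and Hox groups 9 to 13 turned to 13, or to 22.25 with 1 member per 200 kb as well. Other lists without a call changed side with GC matching: oligodendrocyte and astrocyte genes 47.75, blood and microglia genes 36.5, mesenchyme and meninges genes 55.5 and heart and skeletal muscle genes 40.25.

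With gene body plus 5 kb, roof plate and choroid plexus genes passed the threshold at 78 and liver and gut genes at 20.375, while Hox groups 9 to 13 had 45.25, endothelial and pericyte genes 59.25, blood and microglia genes 45 and mesenchyme and meninges genes 51. With 10 kb on each side of the start site, roof plate and choroid plexus genes passed at 80.5. There Hox groups 9 to 13 had 48.5, endothelial and pericyte genes 51, blood and microglia genes 41.5 and mesenchyme and meninges genes 59. With −log10 q of at least 5, endothelial and pericyte genes had 50.5.

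The difference between hindbrain and forebrain regulators kept its call under all 10 alternatives (permutation adjusted p from 0.00084 to 0.0161). That between the Hox groups lost it with 1 member per 200 kb (19.75), where 4 genes remained in each. With GC matching it was 84 (permutation adjusted p = 9.0e-05), with members that share windows. Hindbrain regulators against housekeeping genes differed by -6 with 50 kb, by -0.5 with −log10 q of at least 5, and by 16.75 with GC matching, which passed the threshold (permutation adjusted p = 0.0161; 0.0161 to 0.989 over all alternatives).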

Other observations

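The tests of CpG-rich promoters on X, of the technical replicates and of common cut-offs were chosen after their results were seen. Matching the gene lists on GC content was planned before the data were examined, but what it would show was written down only after its values were seen, and its use in each replicate's own list was added later. The other tests of X and the test of the strongest peaks were set before their results were seen.

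Chromosome X was covered 0.0864 times as much as the median autosome. The GC content and length of its genes did not account for all of this, since X genes lay at a median percentile of 30.5 among 200 autosomal genes matched on both (29.5 and 29.6 in the replicates' own lists). A lack of CpG-rich promoters did not either: 38.6% of 228 such genes on X had a peak 1 kb downstream of the start site, against 71.4% on autosomes, a ratio of 0.540. Repeats were also too small a factor, as X had a ratio of 0.110 over bases outside annotated repeats. Weaker signal on X that leaves more sites under a fixed peak threshold stays open, as do explanations that were not tested. X peaks within 2 kb of CpG-rich promoters had 0.766 times the median signal value of autosomal ones. This ratio holds only peaks past the threshold. A lower number of active X copies per cell may give a weaker signal, but the design holds no single-sex group and no biological explanation was tested.

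A gene's coverage rose with GC content, so the gene lists were compared again with random lists matched on GC content and length. This argued against GC content as the whole explanation for 4 lists, which were past the threshold in the replicated list and in each replicate's own list. Their medians were 88 for hindbrain regional regulators, 97 for Hox groups 1 to 4, 91.75 for neural progenitor genes and 91.75 for pan-neuronal genes. The medians of the other 3 fell but stayed above 50: from 79 to 71.5 for hindbrain neuron subtype genes, from 79.5 to 71.25 for housekeeping genes and from 85.25 to 64.5 for signalling genes. Their permutation adjusted p were 0.0493, 0.0685 and 0.396, and none was under 0.05 in either replicate's own list. For housekeeping and signalling genes, loss of the call is the outcome written down for GC content as the cause. Their high coverage was therefore not separated from GC content. For hindbrain neuron subtype genes the question stays open. No biological explanation was tested.

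Replicate 1 had 1.203 times as many peaks as replicate 2 and covered 1.37 times as many bases. Both lists reached down to about the same −log10 p, 2.01 in replicate 1 and 2.02 in replicate 2. This argues only against a lower −log10 p cut-off in replicate 1. It does not show whether peaks of lower signal value were called there, since depth is unknown and can change −log10 p. The same limit holds for the common cut-offs below. The strongest 50000 peaks of replicate 1 covered 1.33 times as many bases as those of replicate 2. A lower cut-off could also widen strong peaks, so this ratio alone does not decide. Above common −log10 p cut-offs of 3 and 5, replicate 1 still had 1.19 and 1.15 times as many peaks. A difference in depth stays open, since depth is unknown. The number of technical replicates and control libraries cannot be told apart from the replicates themselves, because each replicate has its own (the ratio of 1.203 is 1 contrast between 2 libraries), and no biological explanation was tested.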
